A study of Mus musculus with 24 samples.

How the data were processed

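Cells were sorted from the bone marrow of C57BL/6 mice of both sexes, 8 to 12 weeks old, as lineage-negative, Kit-positive, Sca-1-positive, CD150-positive and Flt3-negative cells, and divided by CD34 and CD48 into HSC, MPP1 and MPP2. KO and Het mice carried an inducible Cre and received 8 injections of tamoxifen at 0.15 mg/g over 16 days, while Sham mice received corn oil. Marrow of several mice was pooled before each sort, so that p-values measure the spread between pooled samples, not between mice. RNA was sequenced as rRNA-depleted stranded libraries with paired-end reads of 50 bp. The replicates are numbered 1, 2_3 and 4, and Sham lacks number 1.

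The deposited values per library are raw counts per gene for 23364 gene symbols, with no normalization by the authors. Per the submitters' processing notes the tools were FastQC, Trimmomatic 0.33, TopHat2 2.0.9, Bowtie 1.0.0, featureCounts, edgeR and R 3.1.2, and the genome build was mm9. A deposited table of the whole series holds a normalized signal for 12186 genes in 24 columns. Its columns sum to 960800 to 1028000. After a single factor per column their sorted values, the lowest left out, lie within 0.992 to 1.01 of the mean for their rank, as after quantile normalization and a scaling per column, which is read from the values and not stated by the authors. Its log2 values correlated with log2 CPM of the counts at 0.998 to 1 across genes of a library, where genes are not independent replicates. That table was used for a single alternative, and 0 columns of per-sample values were left unused. Positions are those of the mm9 assembly with a GENCODE annotation, in which 21217 of the symbols were found.

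Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr by group with its least count of 10, which left 21456, and libraries were scaled by TMM. A single quasi-likelihood model with robust dispersion gave each of the 9 groups its mean and left 15 residual degrees of freedom, with a common dispersion of 0.466. Each comparison was a two-sided quasi-likelihood F test, adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Errors of log2 changes are approximate standard errors, taken as the absolute log2 change divided by the square root of its F statistic. They were not estimated directly by the model. For log2 CPM a prior count of 2 was used. KO against Het in each cell type was the main comparison, since Het mice received the same tamoxifen. KO against Sham, Het against Sham, cell types among Het libraries and the difference of the KO effect between cell types were also tested. Library totals ran from 18823971 to 53196624 counts.

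Gene lists were fixed before the data were examined, as were the tests, the naming rule and all alternatives except where stated. The ribosomal protein list was chosen because the series title names these genes, so its choice may reflect the authors' own results from these libraries. There were 21 lists, of which 20 had members tested: 78 cytosolic ribosomal proteins, 76 mitochondrial ribosomal proteins, 40 genes of ribosome biogenesis and RNA polymerase I, 37 translation factors, 73 nuclear-encoded oxidative phosphorylation genes, 37 p53 targets, 42 stem cell identity and quiescence genes, 30 megakaryocyte and erythroid, 23 granulocyte and monocyte, 23 lymphoid, 33 S phase, 36 G2 and M phase and 36 interferon response genes, 30 immediate early and dissociation stress genes, and markers of neutrophils (13), B cells (11), T and NK cells (12), macrophages (13), late erythroid cells (9) and stroma and endothelium (14). The list of mitochondrially encoded mRNAs had 0 members in the counts. The granulocyte and monocyte list shares 1 gene with the T and NK cell list and 1 with the macrophage list, and the lymphoid list shares 3 with the B cell and 2 with the T and NK cell list. Lists were tested with camera, a test of a list against all other genes, at its preset correlation of 0.01 and again with an estimated correlation, adjusted over the 20 lists of a comparison. Members were counted over all genes and adjusted over the list alone. The mean of a list per library was compared between KO and Het by an exact two-sided permutation test, whose smallest p for 3 against 3 is 0.1.

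Genes were named by rule. For KO against Het these were the 8 largest rises and 8 largest falls among genes past the threshold with a mean of at least 5 CPM in the higher group and no overlap between the groups, plus up to 4 passing members of each list by adjusted p, or up to 2 as values where none passed. Chance gives no overlap in 10% of genes for 3 against 3, and 126 genes in HSC, 11 in MPP1 and 86 in MPP2 met these conditions. For other comparisons the 5 largest rises and falls were named, and for the interactions the 5 smallest adjusted p. Symbols of predicted genes, clones and small RNAs were passed over. Sort marker genes were read as a check. A gene that the rule selects is not reported here.

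Whether equal replicate numbers pair the libraries was checked by the correlation of residuals. Between KO and Het of a cell type 5 of 9 pairs had a correlation over 0.1 (-0.257 to 0.449), which neither shows nor excludes pairing. The main model is not paired. Between cell types of a genotype 16 of 18 pairs did (0.022 to 0.755), among them every pair of HSC and MPP2, so the blocked count is given beside that interaction. Libraries of unequal number were not compared, so these values alone do not show pairing. The alternatives were RLE scaling, TMM without ribosomal protein genes, no filter, a filter of 1 CPM in 3 libraries, replicate number as a block, DESeq2 1.42.0 without independent filtering, limma-trend on the deposited table after adding 1, fits with only the cell types compared, Het and Sham together as control, the estimated correlation and leaving out each library in turn. Where this leaves a Sham group with 1 library, that library is assumed to vary like the other groups. A fit without HSC KO library 1 and HSC Het library 2_3 was added after seeing the data, because they had the fewest detected genes.

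The method was tested on simulated data for KO against Het in HSC, with 100 genes changed by 2 and 100 by 4 fold among 20836. edgeR recovered 47 and 86 of them, with 5 unchanged genes among 138 called. Without both HSC libraries it recovered 21 and 77 (6 unchanged among 104), DESeq2 recovered 49 and 90 (41 unchanged among 180) and limma-trend 43 and 86 (13 unchanged among 142). A simulated list shifted by -0.36 gave a mean of -0.27 and a camera p of 2.01e-09 (8.94e-07 with an estimated correlation), and an unshifted list a p of 0.432 (0.339). The simulated genes were drawn independently, whereas the real ribosomal protein list had an estimated correlation of 0.633 in HSC. The simulation therefore cannot test the preset correlation for lists of correlated genes. It was run once, with the same dispersion of a gene in every library, while replicates of the real HSC groups correlated least. For limma-trend the simulated input was log2 CPM, not a table like the deposited one. These counts are thus no error rates for the real HSC fits.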

Results

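RNA sequencing libraries were made from 3 populations of mouse bone marrow cells sorted by surface markers: haematopoietic stem cells (HSC, CD34-negative and CD48-negative), MPP1 multipotent progenitors (CD34-positive, CD48-negative) and MPP2 progenitors (CD34-positive, CD48-positive). Each population was taken from tamoxifen-treated mice in which both floxed alleles of Mysm1 were open to deletion (KO, n = 3 libraries), from tamoxifen-treated mice with a single floxed allele (Het, n = 3) and from floxed mice given corn oil (Sham, n = 2). Mysm1 encodes a deubiquitinase that acts on histone H2A. The question addressed was how ribosomal protein mRNAs and other transcripts differ in these cells after loss of Mysm1. The 24 libraries held 18823971 to 53196624 counts each, and 21456 of 23364 genes were tested. The 15740 genes detected in HSC KO library 1 and the 15932 in HSC Het library 2_3 were the fewest, against up to 21150 in MPP2 KO library 2_3.

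Mysm1 itself (mm9, chromosome 4, 94608731 to 94645791, minus strand) gave similar whole-gene levels in all groups. In HSC it stood at 110.7 ± 12.8 CPM (counts relative to the TMM-scaled library size, SD, n = 3) in KO, 125.3 ± 14.7 (n = 3) in Het and 117.6 ± 5.22 (n = 2) in Sham. In MPP1 the levels were 100.8 ± 21.8, 116 ± 1.87 and 119.4 ± 0.337 CPM, and in MPP2 they were 94.4 ± 7.31, 105 ± 6.74 and 108.7 ± 1.15 CPM. The log2 change of KO against Het was -0.18 in HSC (adjusted p = 0.635), -0.20 in MPP1 (adjusted p = 0.655) and -0.15 in MPP2 (adjusted p = 0.993). Exon 3, the deleted part, spans 71 bp (94639609 to 94639679), which is 0.957% of the 7420 bp of its 20 exons. Loss of the reads of exon 3 alone would therefore hardly change counts over the whole gene. Whether the deletion changes the level of the rest of the transcript was not tested, nor was its completeness. Counts per exon were not analysed here.

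In HSC, 16 of 78 mRNAs of cytosolic ribosomal proteins fell and 6 of 37 p53 target mRNAs rose in KO against Het (n = 3 and 3). Rpl36a, a protein of the large ribosomal subunit (chromosome X, 131120193 to 131122601), fell by 0.99 ± 0.15 on the log2 scale (SE), from 592.7 ± 42.6 CPM (SD) in Het to 297.6 ± 24.9 in KO (adjusted p = 0.00144). Rpl37a (chromosome 1, 72757834 to 72760383) fell by 0.93 ± 0.15 (adjusted p = 0.0031) and Rps15 (chromosome 10, 79755176 to 79756859) by 0.80 ± 0.13 (adjusted p = 0.00406). Of the 78 cytosolic ribosomal protein genes tested, 16 fell, 0 rose and 62 did not pass, and adjusted over the list alone 36 fell. The list's mean log2 change was -0.36, with 73 of 78 members below 0 (camera adjusted p = 3.93e-27). The call was lost with a correlation taken from the data (adjusted p = 0.221 with an estimated correlation). Each KO library had a lower list mean than each Het library, and the exact permutation p of 0.1 is the smallest that 3 against 3 allow. Another split of the same 6 libraries, which mixes KO and Het, gave a list mean nearly as large, -0.338. Among 37 translation factors the ribosome-bound scaffold Gnb2l1 fell by 0.61 ± 0.14 (adjusted p = 0.0397), 36 did not pass, and adjusted over the list alone 2 fell.

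Of 37 p53 target genes, 6 rose, 0 fell and 31 did not pass in KO HSC, and adjusted over the list alone 10 rose and 1 fell. The mean log2 change was 0.53 (camera adjusted p = 9.21e-07, and adjusted p = 0.00446 with an estimated correlation). Psrc1, a microtubule-associated protein (chromosome 3, 108186757 to 108191149), rose from 8.37 ± 0.574 to 30.2 ± 3.29 CPM, a log2 change of 1.85 ± 0.21 (adjusted p = 2.68e-05). Eda2r, a death receptor of the TNF family, rose by 2.20 ± 0.47 (adjusted p = 0.0269), Zmat3 by 1.29 ± 0.25 (adjusted p = 0.0143), the pro-apoptotic Bax by 1.02 ± 0.22 (adjusted p = 0.0234) and cyclin G1, Ccng1, by 0.74 ± 0.16 (adjusted p = 0.0267). For Cdkn1a, the cell cycle inhibitor p21, the log2 change was 3.33 with adjusted p = 0.056, short of the threshold. It ran from 2.65 to 5.45 over 11 alternatives (adjusted p of 0.00129 to 0.308) and passed in 3: with replicate number as a block (0.0171), by DESeq2 (0.00132) and, at 5.45, without HSC Het library 1 (0.00129).

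**Figure D1:**
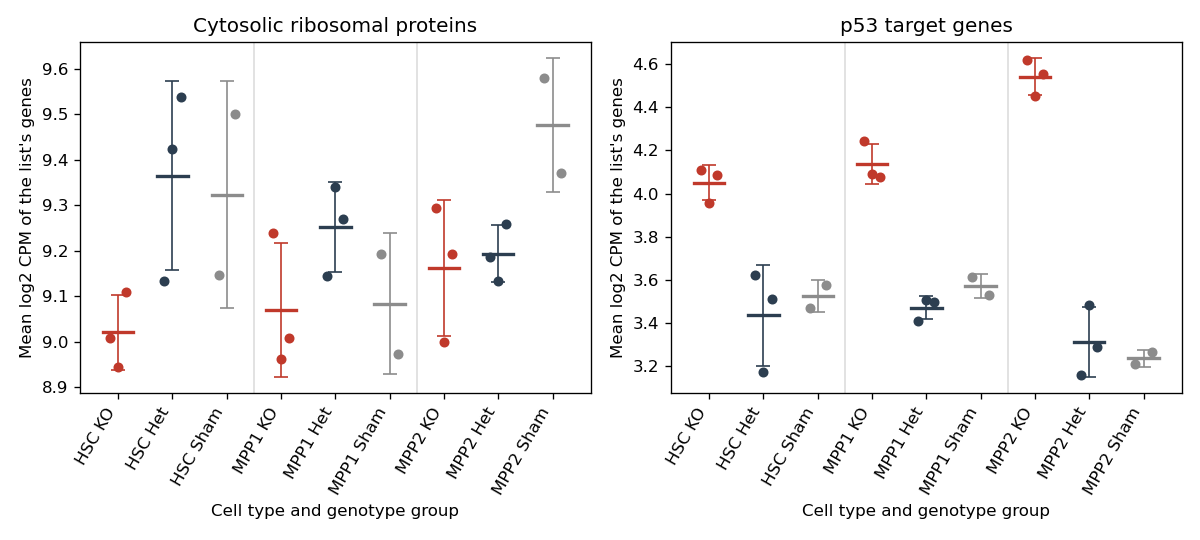
Mean log2 CPM of the cytosolic ribosomal protein list and of the p53 target list in each of the 24 libraries, by cell type and genotype. Points are libraries, bars are group means and error bars are the SD. The p53 list means of the 3 KO libraries lie above those of the 3 Het libraries in every cell type, and the ribosomal protein means lie below them in HSC.

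Some cell cycle genes also rose in KO HSC. Of 33 S phase genes 5 rose, including Mcm2, a subunit of the replicative helicase (0.88 ± 0.20, adjusted p = 0.0323), the primase subunit Prim1 (1.17 ± 0.27, adjusted p = 0.0422) and the histone chaperone subunit Chaf1a (0.74 ± 0.18, adjusted p = 0.0438). The other 28 did not pass, and 28 rose adjusted over the list alone. Of 36 G2 and M phase genes Cdc20 (1.40 ± 0.31, adjusted p = 0.0414) and Ndc80 (1.10 ± 0.26, adjusted p = 0.0474) rose, 34 did not pass, and 32 rose adjusted over the list alone. Their mean log2 changes were 0.83 and 1.28 (camera adjusted p = 1.81e-24 and 8.48e-31), and both had an adjusted p = 0.179 with an estimated correlation. KO and Het libraries overlapped in the S phase mean (exact permutation p = 0.2) but not in the G2 and M phase mean (0.1). Outside the lists the kinetochore genes Cenpk (2.09 ± 0.32, adjusted p = 0.00255) and Cenpm (1.90 ± 0.37, adjusted p = 0.0129), the histone chaperone Asf1b (1.97 ± 0.34, adjusted p = 0.00677) and Fam64a (2.07 ± 0.39, adjusted p = 0.0169) also rose.

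The list of stem cell identity and quiescence genes had a mean log2 change of -0.40 in KO HSC (camera adjusted p = 1.84e-08, but adjusted p = 0.221 with an estimated correlation). Of its 42 members 3 fell, 0 rose and 39 did not pass, while adjusted over the list alone 10 fell and 1 rose. The members that fell were the sulfotransferase Sult1a1 (-2.23 ± 0.39, adjusted p = 0.00938), the cytokine signalling inhibitor Socs2 (-1.68 ± 0.36, adjusted p = 0.0248) and the thioredoxin inhibitor Txnip (-0.71 ± 0.16, adjusted p = 0.032). Gp5, a platelet membrane glycoprotein, rose by 1.60 ± 0.32 (adjusted p = 0.0219) as the only passing member of the 30 megakaryocyte and erythroid genes. The largest rise under the naming rule was that of Gem, a small GTPase (3.13 ± 0.58, adjusted p = 0.0254), with 153.2 ± 89.9 CPM in KO and 17.5 ± 3.63 in Het. The largest falls were those of the tensin gene Tenc1 (-2.86 ± 0.57, adjusted p = 0.027) and the BMP receptor Bmpr1a (-2.65 ± 0.61, adjusted p = 0.0381). Lhcgr (-2.17), Trib2 (-2.09), Plxdc2 (-2.09), Sema7a (-1.90) and Ifitm1 (-1.87) also fell, with adjusted p between 0.00257 and 0.0258, and AI504432 rose by 1.80 (adjusted p = 0.00978).

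In all, 132 genes passed in HSC, 69 up and 63 down (3106 at an unadjusted p under 0.05). Over all alternatives that count ran from 4 to 1001. It was several times larger with the replicate block, DESeq2, limma-trend or both controls, and the fit of HSC alone had more falls than rises. A split of the same 6 libraries that mixes KO and Het passed 399 genes, so the count alone does not single out the genotype. Neutrophil markers, which belong to another cell type, had a mean log2 change of -1.28 in KO (13 of 13 below 0, adjusted p = 0.00462, and adjusted p = 0.55 with an estimated correlation), and stroma and endothelium markers one of -1.06 (adjusted p = 0.0313, and adjusted p = 0.534 with an estimated correlation). KO and Het libraries overlapped in the means of both marker lists (exact permutation p = 0.4 and 0.5). The count depended on single libraries: it was 12 without HSC KO library 1, 13 without HSC Het library 2_3, 68 without KO library 2_3, 246 without Het library 4 and 374 without Het library 1. HSC Het library 1 stood apart in Car1, at 175.97 CPM against 17.87 and 5.65 in the other Het libraries and 0.04 to 1.69 in KO. Ermap was at 75.03 CPM in it and at 4.16 to 11.97 in the other HSC libraries. Its megakaryocyte and erythroid list mean of 4.769 log2 CPM was close to the 4.684 of HSC KO library 1. In MPP1 Het library 1 Car1 stood at 88.44 CPM. Without both HSC libraries with few detected genes, a setting chosen after seeing the data, 4 genes passed, 3 of them shared with the 132, and of the 33 named genes Psrc1 and Plxdc2 remained. In that fit the mean log2 changes were -0.32 for the ribosomal protein list (0 members fell), 0.32 for the p53 list (1 rose), 0.38 and 0.71 for the S and the G2 and M lists (0 rose), -0.35 for the stem cell list (0 fell) and 0.009 for the neutrophil markers. Mcm2 was then at 0.45, Prim1 at 0.78, Chaf1a at 0.48, Cdc20 at 0.92, Cenpm at 1.13 and Asf1b at 1.28. Leaving out single libraries left 6 of the 33 named genes past the test without KO library 1, 6 without Het library 2_3, 18 without KO library 2_3, 25 without KO library 4, 30 without Het library 1 and 24 without Het library 4. The p53 list mean was 0.34 without KO library 1, and its call held in every fit with a library left out.

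In MPP1, the p53 targets Psrc1 and Ccng1 rose and the ribosomal protein gene Rpl36a fell in KO against Het (n = 3 and 3), among 12 genes that passed (7 up, 5 down, and 1860 at an unadjusted p under 0.05). Psrc1 rose from 12.8 ± 2.54 to 40.3 ± 7.96 CPM (1.66 ± 0.21, adjusted p = 0.000208) and Ccng1 by 0.93 ± 0.16 (adjusted p = 0.0178). Gem rose by 4.06 ± 0.61 (adjusted p = 0.0198), Ier5 by 1.01 ± 0.18 (adjusted p = 0.0178), the integrin subunit Itgb2 by 0.98 ± 0.19 (adjusted p = 0.0288) and vimentin, Vim, by 0.82 ± 0.16 (adjusted p = 0.029). Sult1a1 fell by 2.27 ± 0.40 (adjusted p = 0.0217), Plxdc2 by 1.85 ± 0.30 (adjusted p = 0.0178), the blood group gene Art4 by 1.74 ± 0.31 (adjusted p = 0.0408), Rpl22l1, a paralogue of the ribosomal protein gene Rpl22, by 1.21 ± 0.22 (adjusted p = 0.0198) and Rpl36a by 0.84 ± 0.15 (adjusted p = 0.0178).

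The p53 list in MPP1 had a mean log2 change of 0.66 (camera adjusted p = 2.35e-15, and adjusted p = 3.25e-05 with an estimated correlation). Of its 37 members 2 rose, 0 fell and 35 did not pass, and adjusted over the list alone 15 rose. The ribosomal protein list had a mean of -0.18 (49 of 78 below 0, camera adjusted p = 1.01e-05, and adjusted p = 0.656 with an estimated correlation). Of its 78 members 1 fell, 0 rose and 77 did not pass, and adjusted over the list alone 17 fell. Without MPP1 KO library 2_3 that mean was -0.12 and no longer passed (adjusted p = 0.0714, within 2.22e-15 to 0.0714 over the libraries left out). The median log2 change of all genes was -0.11 in this comparison, against which the list mean is to be read. Neutrophil markers had a mean of -1.49 (13 of 13 below 0, adjusted p = 0.00471, and adjusted p = 0.656 with an estimated correlation). KO and Het libraries overlapped in the means of the ribosomal protein and neutrophil lists (exact permutation p = 0.2 for each). The S phase and G2 and M phase lists had means of 0.43 and 0.52 with 0 members past the test, over all genes or adjusted over the list alone (adjusted p = 0.434 and 0.527 with an estimated correlation). With RLE scaling 11 genes passed, 5 up and 6 down. Over all alternatives the count ran from 1 to 116. DESeq2 and limma-trend passed more genes than the main fit, with more falls than rises. The count was 1 without MPP1 KO library 1, 6 without KO library 2_3, 5 without KO library 4, 24 without Het library 1, 4 without Het library 2_3 and 1 without Het library 4, and of the 11 named genes Psrc1 alone passed in each of these fits.

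In MPP2, 14 of 37 p53 target genes rose in KO against Het (n = 3 and 3), and the mean of this list was the highest of the 20. Of the other members Ptpn14, a tyrosine phosphatase, fell (-1.75 ± 0.29, adjusted p = 0.00304), and 22 did not pass. Adjusted over the list alone 23 rose and 1 fell. The mean log2 change was 1.16 (camera adjusted p = 3.92e-44, and adjusted p = 3.28e-08 with an estimated correlation). Cdkn1a (chromosome 17, 29227924 to 29237667) rose from 0.855 ± 0.36 to 20.3 ± 2.13 CPM, a log2 change of 4.57 ± 0.84 (adjusted p = 0.00783). Ccng1 (chromosome 11, 40562054 to 40568813) rose by 1.56 ± 0.17 (adjusted p = 5.21e-06), Zmat3 (chromosome 3, 32233718 to 32264600) by 2.29 ± 0.26 (adjusted p = 1.29e-05), Eda2r (chromosome X, 94529179 to 94572555) by 3.66 ± 0.49 (adjusted p = 0.000297), Psrc1 by 1.79 ± 0.21 (adjusted p = 1.29e-05) and Phlda3 by 3.52 ± 0.79 (adjusted p = 0.0428).

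Of the 78 ribosomal protein genes none passed in MPP2 by edgeR, and adjusted over the list alone 2 fell. At -0.03 the mean log2 change of that list was near 0 (camera adjusted p = 0.267) and depended on single libraries. Its sign turned without MPP2 KO library 2_3 (0.045, adjusted p = 0.113) and without MPP2 Het library 4 (0.004, 0.759), while the list passed below 0 without KO library 1 (-0.10, 0.000218) and without Het library 2_3 (-0.06, 0.025), within 0.000218 to 0.759 over the libraries left out. Rpl36a had a log2 change of -0.61 (adjusted p = 0.0599) and Rpl37a one of -0.62 (adjusted p = 0.0612), while Rpl22l1 fell by 1.16 ± 0.22 (adjusted p = 0.00654). Other genes that rose were Gem (3.92 ± 0.61, adjusted p = 0.00603), the extracellular sulfatase Sulf2 (3.38 ± 0.59, adjusted p = 0.00304), the MAP kinase phosphatase Dusp4 (2.92 ± 0.46, adjusted p = 0.00294), Gas6, a ligand of the TAM receptor kinases (2.69 ± 0.42, adjusted p = 0.000916), and the sialomucin Podxl (2.62 ± 0.47, adjusted p = 0.0147). Amigo2 (-2.18 ± 0.29, adjusted p = 0.000105), Trib2 (-2.05 ± 0.38, adjusted p = 0.0158) and Ppm1l (-1.41 ± 0.29, adjusted p = 0.0134) fell.

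**Figure D2:**
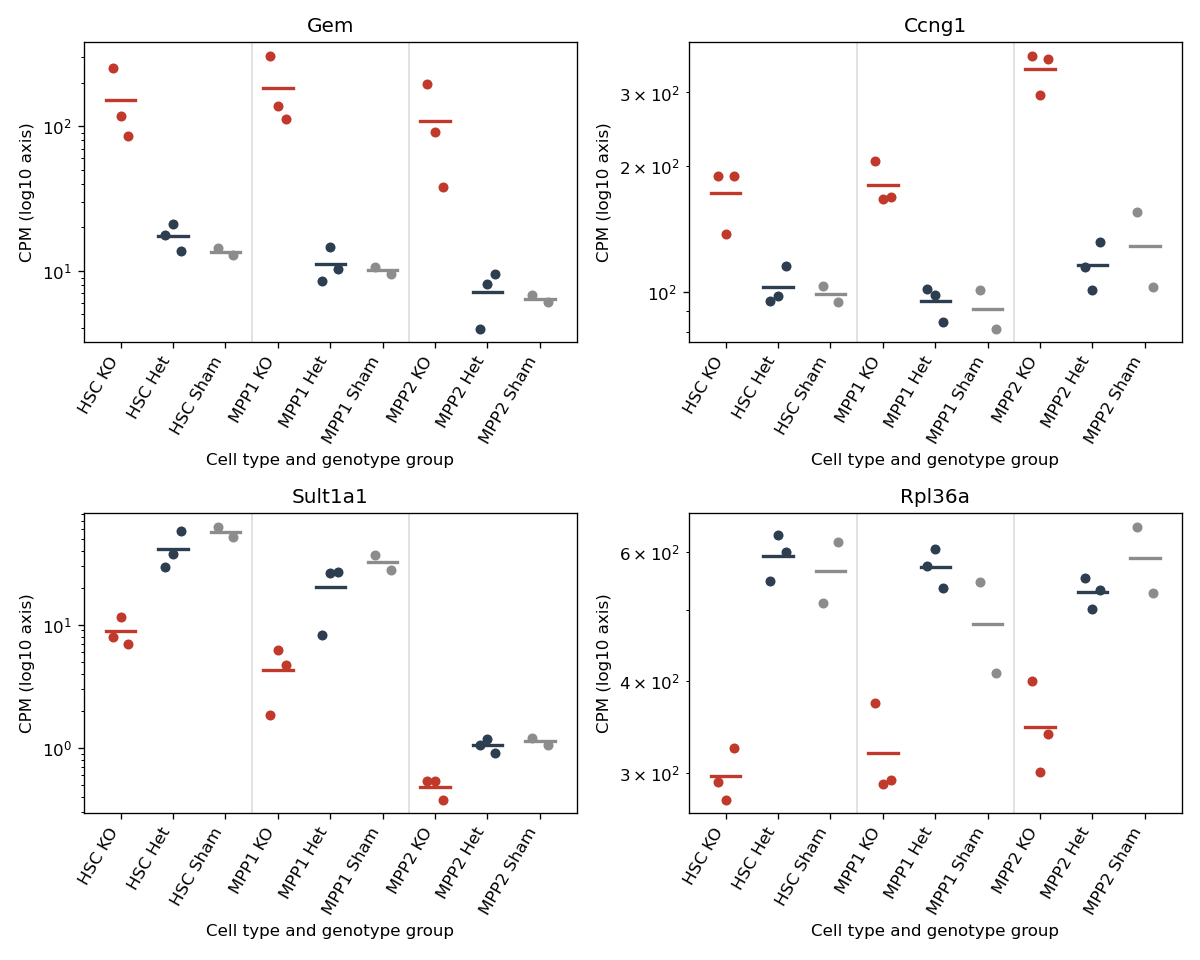
CPM of Gem, Ccng1, Sult1a1 and Rpl36a in each library on a log10 axis, by cell type and genotype, with points for libraries and bars for group means. Mean Ccng1 in MPP2 is 340.9 CPM in KO and 115.9 in Het, and mean Rpl36a in HSC is 297.6 and 592.7 CPM.

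Of 42 stem cell identity genes in MPP2 the RNA-binding protein gene Msi2 rose (0.73 ± 0.14, adjusted p = 0.00727), 0 fell and 41 did not pass. Adjusted over the list alone 7 rose, and the list mean was 0.27 (camera adjusted p = 2.52e-07, but adjusted p = 0.326 with an estimated correlation). KO and Het libraries overlapped in this mean (exact permutation p = 0.2). A Het library stands apart in granulocyte genes: MPP2 Het library 2_3 had 2189 CPM of the granule enzyme gene Mpo, against 71.3 and 184 in the other Het libraries and 42.0 to 78.1 in KO. In the granulocyte and monocyte list (23 genes) the mean log2 change was -1.93, and 1 member fell, the transcription factor Irf8 (-2.91 ± 0.65, adjusted p = 0.0382), with 5 down adjusted over the list alone (camera adjusted p = 4.01e-07, but adjusted p = 0.326 with an estimated correlation). In the lymphoid list (23 genes) Satb1, a chromatin organiser, fell (-2.70 ± 0.53, adjusted p = 0.0166), and Il2rg, the common cytokine receptor chain, rose (1.16 ± 0.26, adjusted p = 0.0293). Neutrophil markers had a mean of -2.09 (13 of 13 below 0, adjusted p = 4.01e-07, and adjusted p = 0.326 with an estimated correlation), and H2-Aa, an MHC class II gene of the B cell list, rose by 1.85 ± 0.30 (adjusted p = 0.00122). Without that library the changes were -1.44 for Irf8 (adjusted p = 0.744, within 0.000796 to 0.744 over its alternatives), -1.29 for Satb1 (0.263, within 6.7e-05 to 0.263) and 1.25 for Il2rg (0.0544, within 0.0124 to 0.51). H2-Aa kept its rise, at 1.87 (0.0102, within 2.09e-05 to 0.0261). The granulocyte and monocyte mean was then -0.48, the neutrophil mean -0.89 (adjusted p = 0.00206), the stem cell mean 0.43 with 3 members up, and the p53 list mean 1.42.

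In MPP2 89 genes passed, 81 up and 8 down (1207 at an unadjusted p under 0.05). The count was 37 without MPP2 KO library 1, 39 without Het library 1 and 55 without Het library 4, and 83 without Het library 2_3, of which 61 were shared. Of the 22 named genes, 11 passed in every fit with a library left out: Ccng1, Zmat3, Psrc1, Eda2r, Sulf2, Dusp4, Gas6, Ier5 (1.26 ± 0.18, adjusted p = 0.00023), H2-Aa, Amigo2 and Ptpn14. Cdkn1a did not pass without MPP2 Het library 1 (adjusted p = 0.107) or Het library 4 (0.081), within 2.11e-07 to 0.107 over its alternatives. Of the 22, 14 passed without KO library 1, 16 without KO library 2_3, 18 without KO library 4, 14 without Het library 1, 17 without Het library 2_3 and 18 without Het library 4.

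Whether the effect of the KO differed between cell types was tested by interaction. For MPP2 against HSC, 7 genes had a higher log2 change in MPP2 (1565 at an unadjusted p under 0.05). Gas6 differed by 3.30 ± 0.57 and the kinase gene Nrk by 3.32 ± 0.58, and the potassium channel gene Kcnk5 by 1.59 ± 0.27 (adjusted p = 0.0198 for each). Glipr2 differed by 1.99 ± 0.37 and Pik3cd, a catalytic subunit of phosphoinositide 3-kinase, by 1.35 ± 0.26 (adjusted p = 0.0435 for both). Such a difference can hold a rise in MPP2, a fall in HSC or both. Gas6 itself rose by 2.69 in MPP2. Libraries of equal number had correlated residuals in every pair of HSC and MPP2, but unequal numbers were not compared. With equal numbers of a genotype taken as a pool and each pool as a block, 118 genes passed, 81 up and 37 down, the 7 among them. The count was 0 without HSC KO library 4, HSC Het library 4, MPP2 KO library 1, MPP2 KO library 2_3 or MPP2 Het library 1, 1 without HSC KO library 2_3 or HSC Het library 2_3, 2 without HSC KO library 1 or MPP2 KO library 4, 3 without MPP2 Het library 4, 19 without MPP2 Het library 2_3 and 50 without HSC Het library 1. Without both HSC libraries with few detected genes 1 gene passed, and with RLE scaling 3 did. The p53 list rose more in MPP2 than in HSC, by a mean log2 difference of 0.63 (adjusted p = 1.54e-08, and adjusted p = 0.000938 with an estimated correlation), and more than in MPP1, by 0.50 (1.16e-05, and adjusted p = 0.00702 with an estimated correlation). These list tests had no block, and they were not repeated with a block or with a library left out. For MPP1 against HSC and for MPP2 against MPP1, edgeR passed 0 genes (1044 and 512 at an unadjusted p under 0.05), while DESeq2 passed 23 and 14. With the pool as a block edgeR passed 0 and 9, the 9 all higher in MPP2, and without that block 7 passed for MPP2 against MPP1 without MPP1 Het library 1.

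Against the Sham libraries (n = 2), KO HSC showed 490 genes past the test, 408 up and 82 down (3195 at an unadjusted p under 0.05). The KO libraries are the same as in the comparison with Het, so this is not an independent repeat. Gem (3.50 ± 0.70, adjusted p = 0.0188), the protease inhibitor Serpine2 (3.31 ± 0.82, adjusted p = 0.0473), galectin 1, Lgals1 (3.1 ± 0.68, adjusted p = 0.0239), Depdc1a (2.83 ± 0.50, adjusted p = 0.00871) and cyclin A2, Ccna2 (2.78 ± 0.55, adjusted p = 0.0175) rose. Tenc1 (-2.98), Ephb4 (-2.77), Sult1a1 (-2.69), Bmpr1a (-2.60) and Zfp53 (-2.27) fell, with adjusted p between 0.00349 and 0.0369. Of the 78 ribosomal protein genes 15 fell and 0 rose, with 29 down adjusted over the list alone and a mean of -0.33 (camera adjusted p = 2.75e-17, but adjusted p = 0.351 with an estimated correlation). The p53 list had a mean of 0.56, with 5 up, and 9 adjusted over the list alone (adjusted p = 0.0104 with an estimated correlation). The S list had 18 of 33 members up and the G2 and M list 13 of 36, with 30 and 35 adjusted over the list alone (adjusted p = 0.0881 for both with an estimated correlation). The count of genes was 38 without HSC Sham library 2_3, 65 without HSC KO library 1 and 270 without HSC Sham library 4, and 120 without both HSC libraries with few detected genes. Of the 10 named genes 3 passed without HSC KO library 1, without Sham library 2_3 or without Sham library 4.

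Against Sham, KO MPP1 had 26 genes past the test, 17 up and 9 down, and 12 up and 10 down with RLE scaling (2227 at an unadjusted p under 0.05). Gem (4.2 ± 0.73, adjusted p = 0.0329), the adaptor gene Lat2 (2.28 ± 0.40, adjusted p = 0.00938), Psrc1 (1.58 ± 0.24, adjusted p = 0.00383), Zmat3 (1.45 ± 0.29, adjusted p = 0.0329) and Bax (1.43 ± 0.25, adjusted p = 0.00938) rose. Sult1a1 (-2.93), Art4 (-2.18), Plxdc2 (-1.85), Pde1b (-1.61) and Trim47 (-1.33) fell, with adjusted p between 0.00383 and 0.0314. The ribosomal protein list had a mean of -0.02 with 0 of 78 members past the test (adjusted p = 0.746). The p53 list had a mean of 0.56, 4 up, and 13 adjusted over the list alone (adjusted p = 0.000455 with an estimated correlation), and the neutrophil markers a mean of -2.43 (adjusted p = 0.00113, and adjusted p = 0.5 with an estimated correlation). The neutrophil value rests on MPP1 Sham library 2_3, at 5.81 log2 CPM for that list. Sham library 4 stood at 2.156, within the KO libraries (2.032 to 3.161). The count was 0 without MPP1 Sham library 2_3, 1 without Sham library 4, 6 without KO library 1 and 15 without KO library 2_3, so that none of the 10 named genes passed in every fit.

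KO MPP2 against Sham had 135 genes past the test, 105 up and 30 down (1229 at an unadjusted p under 0.05). The p53-regulated kinase Plk2 rose from 0.206 ± 0.291 CPM in Sham to 5.89 ± 2.75 in KO (4.91 ± 0.97, adjusted p = 0.0192). A Sham library without Plk2 counts limits this value, which ran from 3.83 to 10.55 over its alternatives. Sulf2 (4.29 ± 0.74, adjusted p = 0.00246), Cdkn1a (4.25 ± 0.99, adjusted p = 0.0424), Gem (4.08 ± 0.73, adjusted p = 0.0134) and Dusp4 (3.95 ± 0.59, adjusted p = 0.00136) rose. Trib2 (-2.54), Amigo2 (-1.89), Ptpn14 (-1.82), Rab4a (-1.64) and Arhgef25 (-1.56) fell, with adjusted p between 0.00149 and 0.0424. The p53 list had a mean of 1.32, with 8 up and 1 down, and 18 up and 1 down adjusted over the list alone (adjusted p = 3.84e-07 with an estimated correlation). Of the ribosomal protein genes 5 of 78 fell, 28 adjusted over the list alone, with a mean of -0.31 (camera adjusted p = 1.35e-27, but adjusted p = 0.351 with an estimated correlation). B cell markers had a mean of 1.06 (adjusted p = 8.7e-05, and adjusted p = 0.177 with an estimated correlation) and neutrophil markers one of -0.89 (adjusted p = 0.00171, and adjusted p = 0.598 with an estimated correlation). The count was 5 without MPP2 Sham library 2_3, 58 without KO library 1 and 74 without KO library 2_3, and none of the 10 named genes passed without Sham library 2_3, where Arhgef25 was at -0.74 and Rab4a at -0.96.

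Between the controls, Het against Sham, edgeR passed 0 genes in each of HSC, MPP1 and MPP2, with 1485, 207 and 1141 at an unadjusted p under 0.05. DESeq2 passed 78, 5 and 24. In HSC 3 genes passed without HSC Het library 4, 3 without Sham library 2_3 and 1 without Sham library 4, and in MPP2 4 passed without Sham library 4. Even so, the ribosomal protein list differed between these controls with the preset correlation. In MPP2 its mean was -0.28, with 78 of 78 below 0 (adjusted p = 7.08e-21, but adjusted p = 0.29 with an estimated correlation). In MPP1 it was 0.16 (adjusted p = 3.19e-09, but adjusted p = 0.665 with an estimated correlation), and in HSC 0.03 (adjusted p = 0.452). The p53 list means were 0.03, -0.10 and 0.16 in HSC, MPP1 and MPP2, with adjusted p of 0.895, 0.39 and 0.32. The S phase and the G2 and M phase lists were higher in Het than in Sham HSC, with means of 0.30 and 0.62 (adjusted p = 2.45e-05 and 3.61e-08, but adjusted p = 0.905 for both with an estimated correlation) and 0 members past the test. HSC Het library 1 stood highest, at 5.997 and 5.258 log2 CPM for these lists. Het libraries 2_3 and 4 had 5.08 and 5.471 for S phase and 4.188 and 4.242 for G2 and M phase. The Sham libraries had 5.013 and 5.48, and 3.873 and 4.222, and Sham lacks number 1.

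**Figure D3:**
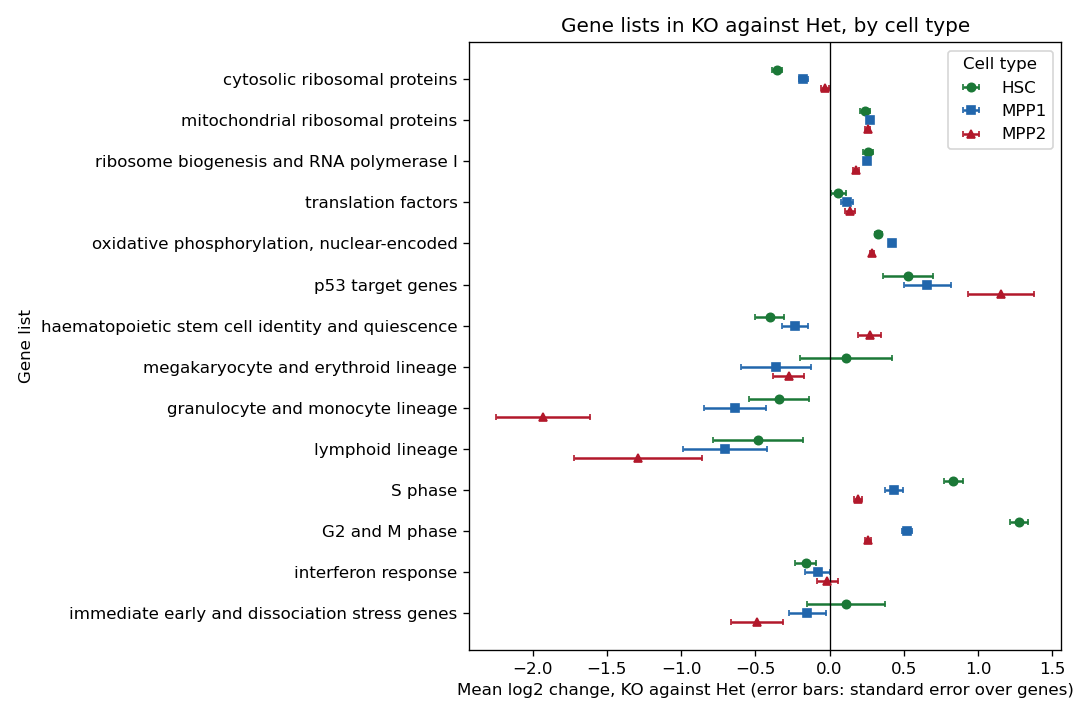
Mean log2 change of KO against Het for 14 gene lists in HSC, MPP1 and MPP2, with error bars for the standard error over each list's genes. The p53 target list lies at 0.53, 0.66 and 1.16, and the cytosolic ribosomal protein list at -0.36, -0.18 and -0.03.

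Among the Het libraries (n = 3 each), 28 of 42 stem cell identity genes were lower in MPP2 than in MPP1. Between MPP2 and MPP1 1606 genes passed, 693 higher and 913 lower in MPP2 (4046 at an unadjusted p under 0.05). Cd48, a marker of the sort, was higher by 4.16 ± 0.89, followed by the immunoglobulin joining chain Igj (3.83 ± 0.94), Atp8b4 (3.64), Clec4d (3.42) and Plac8 (3.29). Sult1a1 (-4.28 ± 0.44), the stem cell surface receptor Procr (-4.19 ± 0.50), Plk2 (-3.94), Nrk (-3.88) and lymphotoxin beta, Ltb (-3.56) were lower. Adjusted p ran from 1.73e-06 to 0.0397. Of the stem cell identity genes 14 did not pass, with 34 down adjusted over the list alone (mean -1.43, adjusted p = 0.00317 with an estimated correlation). Of 36 interferon response genes 15 fell and 21 did not pass, with 21 down adjusted over the list alone (mean -0.74, adjusted p = 0.0312 with an estimated correlation). Of 36 G2 and M phase genes 8 rose, 36 adjusted over the list alone (mean 1.25, camera adjusted p = 8.41e-28, but adjusted p = 0.157 with an estimated correlation), and B cell markers had a mean of -0.92 with 3 down (adjusted p = 0.00039, and adjusted p = 0.157 with an estimated correlation). With the pool as a block 2641 genes passed, 1372 up and 1269 down. The count was 585 without MPP1 Het library 2_3, 668 without MPP1 Het library 4, 717 without MPP2 Het library 1 and 853 without MPP2 Het library 4. Cd48 did not pass without MPP1 Het library 4 (adjusted p = 0.0562, within 4.83e-05 to 0.0562 over its alternatives). Igj and Clec4d did not pass without MPP1 Het library 2_3 (0.108 and 0.0636), MPP1 Het library 4 (0.104 and 0.122) or MPP2 Het library 4 (0.0606 and 0.086), nor Igj without MPP1 Het library 1 (0.051), within 0.00189 to 0.108 and 0.000492 to 0.122 over their alternatives. Atp8b4 did not pass without MPP1 Het library 1 (0.074), 2_3 (0.165) or 4 (0.176) or MPP2 Het library 2_3 (0.316, with a log2 change of 1.24), within 0.00135 to 0.316.

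MPP1 Het cells differed from HSC Het cells in 3 genes, all higher in MPP1, among them Asf1b (2.28 ± 0.35, adjusted p = 0.00681) and Cenpk (1.98 ± 0.32, adjusted p = 0.0127), with 2123 genes at an unadjusted p under 0.05. Of 33 S phase genes 1 rose, 26 adjusted over the list alone, and of 36 G2 and M phase genes 0 rose, 34 adjusted over the list alone. The means were 0.80 and 1.29 (camera adjusted p = 1.51e-24 and 1.79e-32, but adjusted p = 0.131 for both with an estimated correlation). RLE scaling gave 3 genes up and 1 down, and with the pool as a block 341 genes passed, 282 up and 59 down. The 3 genes did not pass without HSC Het library 2_3 or without MPP1 Het library 1, which left 0 genes, and the count was 101 without HSC Het library 1, 15 without HSC Het library 4 and 35 without MPP1 Het library 2_3. As a check of the sort, Cd48 stood at 0.626 to 2.28 CPM in the HSC and MPP1 groups and at 18.5 to 42.0 CPM in the MPP2 groups. Cd34 stood at 75.2 to 88.6 CPM in HSC and 132.4 to 164.4 in MPP1. In MPP2, sorted as CD34-positive, it was 194 ± 67.6 in KO and 143.6 ± 81.4 in Het, but 77.7 ± 37 in Sham, the level of the HSC groups. Ly6a, the gene of Sca-1, stood at 20.6 to 24.3 CPM in HSC, 11.3 to 17.5 in MPP1 and only 1.2 to 6.39 in MPP2. Flt3, which the sort selects against, was at 38.9 ± 51.4 CPM in MPP2 Het, with a highest library at 98.0. Its other group means were 6.92 to 24.9 CPM. Kit stood at 519.9 to 893.3 CPM and Slamf1, the gene of CD150, at 24.6 to 45.3 over all groups.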

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

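The tests of the cell sorts and the fits without both HSC libraries with few detected genes were chosen after the result was seen, and the second choice of genes for the sort tests, by smallest p, was also an addition, as were the match on expression level alone and the splits that keep pools whole.

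A test of the difference between cell types singled out 7 genes, whose KO against Het log2 change was higher in MPP2 than in HSC: Gas6 by 3.30, Nrk by 3.32 and Kcnk5 by 1.59 (adjusted p = 0.0198 each), and Plxdc2 by 2.35, Tgm2 by 1.65, Glipr2 by 1.99 and Pik3cd by 1.35 (adjusted p = 0.0435 each). Plxdc2 and Tgm2 fall outside the naming rule for this test and were named after their values were seen. The difference of Plxdc2 is mostly its fall in KO HSC (-2.09). In MPP2 it stood at 9.76 to 13.88 CPM in KO and 7.96 to 12.14 in Het. Of 60 splits of the KO and Het libraries within each cell type, the real one included, 1 gave as many genes, the real one with 7, and the highest other gave 4. Those splits part libraries of equal number, taken as a pool, whose residuals correlated between HSC and MPP2. The splits that keep every pool whole number 10, too few for a share under 0.05, with 7 genes for the real one and 0 as the highest other. The count was also 0 in 5 fits with a library left out.

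The same test for lists differed for cytosolic ribosomal proteins in each pair of cell types: 0.18 for MPP1 against HSC (adjusted p = 4.62e-09, but adjusted p = 0.933 with an estimated correlation), 0.32 for MPP2 against HSC (4.67e-17, but adjusted p = 0.539 with an estimated correlation) and 0.15 for MPP2 against MPP1 (0.000548, but adjusted p = 0.855 with an estimated correlation). For p53 targets it was 0.13 (0.0427, but adjusted p = 0.74 with an estimated correlation), 0.63 (1.54e-08, and adjusted p = 0.000938 with an estimated correlation) and 0.50 (1.16e-05, and adjusted p = 0.00702 with an estimated correlation) in the same order. Stem cell identity genes differed between MPP2 and HSC by 0.67 (6.18e-18, and adjusted p = 0.0452 with an estimated correlation). None of these list differences was tested with the pool as a block or with a library left out.

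Cytosolic ribosomal protein mRNAs were lower in KO than Het HSC, with a mean log2 change of -0.36. For 76 members, 20 genes each were matched on length, GC content and expression level, although at a mean log2 CPM of 9.19 against 8.32. The matched genes rose by a mean of 0.507, so the difference of -0.862 (SE 0.049 over members, not libraries) holds their rise as well as the members' fall. Matched on expression level alone, the other genes stood at 9.16 and rose by a mean of 0.31, with a difference of -0.665 (SE 0.04 over members). Genes matched on these properties thus rose while the members fell. This argues against length, GC content or expression level as the whole cause. Without HSC KO library 1 and HSC Het library 2_3 the list's mean was -0.32, although no member then passed the test. Both libraries are thus not the whole source of that mean. The fit cannot exclude the number of detected genes as a cause, since HSC Het library 4 with 16894 stayed in it. HSC Het library 1 had 19279, and the KO libraries 2_3 and 4 had 20303 and 19126. The list stood at 9.538 log2 CPM in Het library 4, 9.134 in Het library 1, and 8.945 and 9.109 in those KO libraries. Still open are the correlation between these genes (adjusted p = 0.221 with an estimated correlation), differences between pools and reads shared with pseudogenes, which was not tested, and the preset test also separated Het from Sham MPP2. Loss of Mysm1 may lower these mRNAs, which is a hypothesis found and tested on the same data.

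S phase and G2 and M phase mRNAs were higher in KO than Het HSC, by a mean of 1.06 over 69 members, of which 5 of 33 and 2 of 36 passed, and both lists lost their call (adjusted p = 0.179 with an estimated correlation). Without both HSC libraries with few detected genes it was lower, 0.549 (SE 0.038 over members, not libraries), with 67 of 69 above 0 and 0 members past the test. That is past the bound of 0.5 set before this value was seen by more than 1 SE. The S phase list alone was at 0.376, under the bound, and the G2 and M phase list at 0.708. The members are correlated (estimated correlation 0.711 and 0.818), so this SE cannot decide whether both libraries are the whole cause. Cells of the CD34-positive gate in the KO sort cannot be told apart from cycling within the gate. The first choice of genes for this test, past the threshold as higher in MPP1 than HSC among Sham libraries, held 1 gene. The 100 genes with the smallest p, of which 1 passed, had a mean of 0.74 in KO against Het, and Cd34, which the gate selects against, changed by 0.06 ± 0.41 (adjusted p = 0.995). The genotype stays open as an untested explanation.

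Genes higher in MPP1 than MPP2 among the Sham libraries were higher in KO than Het MPP2, with a mean log2 change of 0.245 ± 0.095 (SE) over the 100 with the largest rise, of which 63 lay above 0. The library MPP2 Het 2_3, which stands apart, could not be the source, since the mean was 0.665 ± 0.106 without it. For cells of the CD48-negative gate in the KO sort, the 100 genes higher in MPP2 than MPP1 had a mean of -0.35 ± 0.073, which that explanation needs, but Cd48 itself was 1.19 ± 0.77 higher (adjusted p = 0.993) and not lower, so these cannot be told apart from a change within MPP2 cells. Sets of 100 genes chosen by smallest p gave 0.025 ± 0.035 for the genes higher in MPP2, and 0.502 for those higher in MPP1 (0.656 without the library), so the first test depends on the choice of genes. In KO against Het HSC both sets of genes higher in MPP1 than MPP2 went the other way. The set with the largest rise had a mean of -1.057 ± 0.075 (9 of 100 above 0), and the set by smallest p one of -0.473 ± 0.052 (14 of 100). The genotype stays open as an untested explanation.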

How the results depend on the processing

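The setting without both HSC libraries with few detected genes was chosen after seeing the data. The p53 target list kept its direction and its call under all alternatives run, with means of 0.32 to 0.69 in HSC, 0.56 to 0.70 in MPP1 and 1.09 to 1.42 in MPP2. TMM without ribosomal protein genes changed none of the results it was run on. Of the alternatives run on 136 values of named genes, 1032 kept direction and side of the threshold, 360 kept the direction but lost the call, 21 gained a call and 0 reversed. Where counts of genes moved, the cause was not tested, except that fewer libraries were in the fits with libraries left out and more control libraries in those with both controls. For KO against Het in HSC (132) the counts were 726 with replicate block, 734 with the block within cell type, 4 without both HSC libraries, 612 by DESeq2, 595 by limma-trend, 1001 with both controls and 12 to 374 with a library left out, and the fit of HSC alone gave 58 up and 83 down. MPP1 (12) gave 35 with either block (19 up and 16 down, or 21 and 14), 81 by DESeq2 (28 up, 53 down), 50 by limma-trend (15 up, 35 down), 116 with both controls and 1 to 24 with a library left out. MPP2 (89) gave 144 by DESeq2, 194 with both controls and 37 to 83 with a library left out. For KO against Sham, HSC (490) gave 311 with no filter, 197 with HSC alone, 120 without both HSC libraries, 987 by DESeq2 and 38 to 600 with a library left out. MPP1 (26) gave 47 with replicate block, 42 with MPP1 alone (22 up, 20 down), 115 by DESeq2 and 0 to 23, and MPP2 (135) gave 259 by DESeq2 and 5 to 162. For Het against Sham (0 each), HSC gave 1 with the block within cell type, 78 by DESeq2 and 0 to 3, MPP1 5 by DESeq2 and 0 to 0, and MPP2 24 by DESeq2 and 0 to 4. MPP1 against HSC (3) gave 11 with no filter, 5 with the stricter filter, 341 with the pool as block, 0 with those cell types alone, 203 by DESeq2 and 0 to 101. MPP2 against MPP1 (1606) gave 2641 with the pool as block, 2546 with those cell types alone and 585 to 2258. For the interactions, MPP1 against HSC (0) gave 23 by DESeq2 and 0 to 0. MPP2 against HSC (7) gave 3 with RLE, 3 with the stricter filter, 118 with the pool as block, 1 without both HSC libraries, 67 by DESeq2 and 0 to 50. MPP2 against MPP1 (0) gave 9 with the pool as block, 14 by DESeq2 and 0 to 7. DESeq2 also called more unchanged genes than edgeR in the simulated data (41 against 5). There each gene had the same dispersion in every library, so this gives no error rate for the real counts. The ribosomal protein list lost its call with an estimated correlation in HSC (-0.36, adjusted p = 0.221) and in MPP1 (-0.18, adjusted p = 0.656), and in MPP1 also against Sham (-0.02, adjusted p = 0.746). In MPP2 it gained a call with both controls (-0.17, adjusted p = 8.72e-13 at the preset correlation) and against Sham (-0.31, adjusted p = 1.35e-27, but adjusted p = 0.351 with an estimated correlation). With both controls the estimated correlation was not run. With a library left out its mean ran from -0.46 to -0.27 in HSC, -0.25 to -0.12 in MPP1 and -0.10 to 0.045 in MPP2, where it gained a call without KO library 1 (adjusted p = 0.000218) and without Het library 2_3 (0.025), and the p53 mean from 0.34 to 0.69, 0.61 to 0.70 and 1.09 to 1.42. The median change of all genes moved by 0.109 with limma-trend in KO against Het MPP1, and by -0.109 with the stricter filter in Het against Sham MPP2. Of the pairs of KO and Het libraries with equal replicate numbers, 5 of 9 had correlated residuals (over 0.1), so pairing is neither shown nor excluded. The main model has no block, and the blocked counts of KO against Het are given here alone.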

Other observations

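The fit without both HSC libraries with few detected genes was chosen after the result was seen.

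Genes of energy metabolism and ribosome assembly had list means above 0 in KO against Het, with 0 members past the test over all genes. The 73 nuclear-encoded oxidative phosphorylation genes had mean log2 changes of 0.33 in HSC (70 above 0), 0.42 in MPP1 (73 above 0) and 0.29 in MPP2 (73 above 0), with 18, 17 and 0 members up adjusted over the list alone. Camera gave adjusted p = 1.3e-10, 3.36e-27 and 3.99e-15, but adjusted p = 0.534, 0.302 and 0.326 with an estimated correlation. Atp5g3, a subunit of ATP synthase, stood at 0.60 in HSC (adjusted p = 0.11) and Cox6c, of cytochrome c oxidase, at 0.66 in MPP1 (adjusted p = 0.248). The 76 mitochondrial ribosomal proteins had means of 0.24, 0.27 and 0.26 in HSC, MPP1 and MPP2, opposite in sign to the cytosolic list, with 0 members past in either count (adjusted p = 0.55, 0.434 and 0.326 with an estimated correlation). The 40 ribosome biogenesis genes had means of 0.26, 0.25 and 0.18, with 3, 0 and 0 up adjusted over the list alone (adjusted p = 0.534, 0.434 and 0.535 with an estimated correlation). In HSC the means were 0.23, 0.15 and 0.10 for these 3 lists without both HSC libraries with few detected genes.

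Genes of ribosome assembly, energy metabolism and lineages also differed between MPP2 and MPP1 Het cells. Of 40 ribosome biogenesis genes 10 rose and 30 did not pass, with 21 up adjusted over the list alone (mean 0.41, camera adjusted p = 3.56e-13, but adjusted p = 0.184 with an estimated correlation). Of 73 oxidative phosphorylation genes 10 rose, 25 adjusted over the list alone (mean 0.38, 2.9e-14, but adjusted p = 0.243 with an estimated correlation). Of 30 megakaryocyte and erythroid genes 4 rose, 8 adjusted over the list alone (mean 1.06, 2.19e-08, but adjusted p = 0.184 with an estimated correlation), and of 23 granulocyte and monocyte genes 4 rose, 10 adjusted over the list alone (mean 1.91, 3.13e-05, but adjusted p = 0.301 with an estimated correlation). The MPP2 Het library 2_3 with 2189 CPM of Mpo is among these libraries. From HSC to MPP1 the stem cell identity genes had a mean of -0.42 with 0 past over all genes and 7 down adjusted over the list alone (adjusted p = 0.0802 with an estimated correlation).

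Other lists in KO against Het gave the following means in HSC, MPP1 and MPP2. Interferon response genes stood at -0.16, -0.08 and -0.02 (adjusted p = 0.0251, 0.425 and 0.267, and adjusted p = 0.55 with an estimated correlation in HSC). Immediate early genes stood at 0.11, -0.15 and -0.49 (adjusted p = 0.59, 0.837 and 0.205). Translation factors stood at 0.06, 0.12 and 0.14 (adjusted p = 0.699, 0.00212 and 0.000676, but adjusted p = 0.656 and 0.601 with an estimated correlation in MPP1 and MPP2). Megakaryocyte and erythroid genes stood at 0.11, -0.36 and -0.28 (adjusted p = 0.0178, 0.422 and 0.554, and adjusted p = 0.569 with an estimated correlation in HSC). Granulocyte and monocyte genes stood at -0.34 and -0.64 in HSC and MPP1 (0.412 and 0.312), and lymphoid genes at -0.48, -0.70 and -1.29 (0.412, 0.422 and 0.554). The stem cell list had a mean of -0.23 in MPP1 (adjusted p = 0.0857). The S phase and G2 and M phase means in MPP2 were 0.19 and 0.26 (adjusted p = 0.00136 and 0.00179, but adjusted p = 0.615 and 0.648 with an estimated correlation). Among other-cell markers, B cell genes stood at 0.31, -0.71 and -0.39 (0.412, 0.642 and 0.17), T and NK cell genes at -0.37, -1.10 and -0.59 (0.901, 0.0994 and 0.156), macrophage genes at 0.20, 0.10 and 0.26 (0.444, 0.563 and 0.177), late erythroid genes at -0.28, -0.55 and -0.25 (0.563, 0.261 and 0.554), and stroma and endothelium genes at -0.83 and -0.40 in MPP1 and MPP2 (0.0637 and 0.17).

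Without MPP2 Het library 2_3, several MPP2 means shifted: megakaryocyte and erythroid genes to -0.42 (adjusted p = 0.0162), immediate early genes to -0.31 (0.542), lymphoid genes to 0.051 (0.064), interferon response genes to 0.094 (0.209), B cell genes to -0.11 (0.07), T and NK cell genes to -0.27 (0.267) and macrophage genes to 0.41 (0.0943). The S phase (0.15) and G2 and M phase (0.20) lists then had adjusted p = 0.116 each, translation factors (0.094) 0.121 and ribosome biogenesis genes (0.12) 0.0463. Without both HSC libraries with few detected genes, HSC means shifted for megakaryocyte and erythroid genes to -0.32 (adjusted p = 0.861), lymphoid genes to 0.30 (0.731), granulocyte and monocyte genes to -0.049 (0.897), interferon response genes to -0.095 (0.115), immediate early genes to -0.068 (0.0687), translation factors to -0.017 (0.378), B cell genes to 1.20 (0.0147), T and NK cell genes to 1.09 (0.0687) and macrophage genes to 0.63 (0.402).

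Other splits of the same libraries were fitted for each comparison of 3 against 3 libraries, whose 10 splits are too few for a share under 0.05. In HSC, 2 of 10 splits gave at least the 132 genes of the real one, and the highest other gave 399, by parting KO libraries 1 and 4 and Het library 4 from the other 3 libraries. That split calls several times the real count, which points to a structure of the HSC samples apart from genotype. The ribosomal protein mean of -0.356 was matched by 1 of 10 splits, itself, with -0.338 as the highest other, and the p53 mean of 0.528 by 1, with 0.332. In MPP1 1 split gave 12 genes, with 0 as the highest other, 2 gave a ribosomal protein mean as large as -0.178, with 0.241, and 1 gave a p53 mean of 0.658, with 0.332. In MPP2 1 split gave 89 genes, with 0 as the highest other, 9 gave a ribosomal protein mean as large as -0.032, with 0.143, and 1 gave a p53 mean of 1.16, with 0.529. For MPP1 against HSC in Het 2 splits gave at least 3 genes, with 4 as the highest other, and for MPP2 against MPP1 1 gave 1606, with 34. For the interactions with 0 genes, all 60 splits gave as many, with 507 as the highest other for MPP1 against HSC and 0 for MPP2 against MPP1. Every split gives at least 0 genes, so this says nothing about chance. The split with 507 exchanges KO and Het in HSC and keeps them in MPP1, and so adds up the KO effects of both.

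The libraries differ along a first principal component that holds 52% of the variance of 11036 genes and a second with 13.8%. Over the libraries the second correlated at 0.753 with the number of detected genes, and the first at 0.003. Replicates of HSC KO correlated at 0.894 to 0.949 and those of HSC Het at 0.889 to 0.907 across genes, the lowest of the 9 groups. The share of counts on cytosolic ribosomal protein genes was 6.34 to 7.88% in HSC KO, 8.02 to 10.5% in HSC Het and 8.82 to 11.2% in HSC Sham.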
